A study of Mus musculus with 16 samples.

How the data were processed

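A total of 16 libraries of adipose tissue from C57BL/6 mice aged 8 weeks were used, in 8 groups of 2. Total RNA (input), RNA captured with an antibody against N6-methyladenosine (m6A) and ribosome-protected fragments (footprints) were sequenced. Input and m6A libraries came from 3 conditions: WT mice kept untreated at room temperature (WT RT), WT mice housed singly for 7 days at 4 °C (WT cold), and mice labelled Mettl3 cKO kept in the same cold (cKO cold). Footprint libraries came from WT cold and cKO cold alone. WT mice carried the floxed Mettl3 allele without Cre, and cKO mice carried it with Adipoq-Cre, which acts in adipocytes, per the labels. The WT RT libraries carry another series of library codes than the cold libraries, so temperature and code series cannot be told apart. WT cold and cKO cold lie within 1 series. The labels do not say that replicates are separate animals, so p-values measure only the spread between these libraries.

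The deposited values are RPKM for 17883 genes in 1 matrix, made by the authors. HISAT2 and the genome build mm10 are named in the submitters' processing notes, without versions. The notes do not state the counting tool, the annotation or which reads the values were scaled to. Gene names and identifiers were taken from the matrix. Of the identifiers, 17871 matched the reference table, and 25 symbols that had been turned into dates were restored from it. All value columns were used and 0 were left out.

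Because an RPKM value is a whole number of reads times 1 constant per library over 1 length per gene, the read numbers were recovered by searching for the constants. Within a tolerance of 0.001 read plus 3e-08 of the reads, values of all 17883 genes (100.0%) were whole in the input and m6A libraries. Of 500 genes with scrambled values, 0 were whole. The scrambled genes were all above 0 in every library and were searched over fewer multiples. Genes above 0 in at most 1 library are whole by construction, so the shares are not directly comparable. Footprint reads were recovered up to a common factor, so their totals are lower bounds, and footprint values share no length scale with the input. Recovered reads numbered 7746445 and 7401865 in the WT RT inputs, 8673393 and 4453872 in the WT cold inputs, and 4511639 and 3895031 in the cKO cold inputs. The m6A libraries held 5723910 and 4883129 reads in WT RT, 6075294 and 6426541 in WT cold, and 5061751 and 5303991 in cKO cold. Footprint libraries held at least 2297896 and 1676208 reads in WT cold and 2009076 and 2461267 in cKO cold. In input and m6A libraries 1 read was worth more where fewer reads were recovered, in nearly exact proportion. For example, 1 read in WT cold input replicate 2 was worth 1.739 times that in WT RT input replicate 1. The input and m6A values are thus shares of the reads on the listed genes. Where a group was at 0, the floor was 3 reads over the group. Floors cover counting error only. The spread between replicates was 4.712 to 18.2 times that of counting alone in input and m6A libraries (chi-square per degree of freedom) and at least 17.87 and 19.86 times in footprints, and log2 values of replicates correlated across genes with Pearson's r of 0.9676 to 0.9923.

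Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend; two-sided), for genes with at least 1 RPKM in at least 2 libraries of the fit. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The 6 input libraries were fitted together, with 3 residual degrees of freedom. The 12 input and m6A libraries were fitted together for m6A enrichment (m6A over input) and its changes, with 6. The 8 cold input and footprint libraries were fitted together for footprints and for translational efficiency (footprints over input), with 4. Changes of enrichment or efficiency were tested as interaction terms. Errors are standard errors of the log2 fold change, with n = 2 libraries per group. The added 1 RPKM shrinks the fold changes of genes with low values. Reads were recovered and figures drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

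Replicate numbers within a condition were checked for pairing. Deviations from the group mean over 8887 genes correlated at 0.487, 0.638 and 0.533 between input and m6A libraries of the same condition and number (WT RT, WT cold, cKO cold), at 0.332 and 0.255 between input and footprints, and at 0.374 and 0.221 between m6A and footprints. Across conditions the correlations ran from -0.17 to 0.184. The numbers were therefore taken to pair libraries within a condition, from the data and not from the labels, and a fit with these pairs as blocks is given wherever it changes a call or moves a count by over 1.5 times. For cKO footprints the pairing is weakly borne out. In cKO replicates 1 and 2, Lep stood at 245 and 119 RPKM in input and at 779 and 273 in footprints, the same way. Acta1 ran the other way, at 1.23 and 40.1 in input and at 82.6 and 2.01 in footprints.

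A total of 33 gene lists with 665 members, of which 648 were in the matrix, were fixed beforehand. They cover thermogenic and beige markers, UCP1-independent heat, complex I, complexes II to V, mitochondrial DNA-encoded mRNAs, fatty acid oxidation, the TCA cycle, de novo lipogenesis, lipolysis and fatty acid uptake, adipocyte markers, KLF transcription factors, m6A writers, erasers and readers, the circadian clock, glucocorticoid-induced genes, immediate early genes, heat shock proteins, the ATF4 response, interferon-stimulated genes, cytosolic ribosomal proteins, the cell cycle, insulin signalling and beta-adrenergic signalling. The rest are markers of macrophages, T and B cells, neutrophils and mast cells, endothelium, fibroblasts, smooth muscle, skeletal muscle, mammary and skin epithelium, the male reproductive tract, red blood cells and Schwann cells. Lists with at least 5 tested members were tested against all other genes with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether members move one way on balance. A further set of m6A-enriched genes was taken from the WT RT input and m6A libraries alone (log2 enrichment of at least 1).

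Genes were named by a fixed rule. Mettl3, Klf9, Pparg, Ucp1, Cidea, Dio2, Elovl3, Ppargc1a and Prdm16 were named whatever their values. The 5 highest and 5 lowest fold changes were named among called genes with a mean of at least 5 RPKM in 1 group and, for comparisons of a pair of groups, no overlap between replicates (predicted genes, small RNAs and pseudogenes aside). Where fewer passed, genes with the smallest unadjusted p were named as not passing. From each list up to 3 called members with the smallest p, or the 1 member with the smallest p, could be named.

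The test was tried on simulated data with 200 genes changed, 50 at each of 4 sizes, drawn from genes with a mean of at least 5 RPKM. The shares do not cover genes with lower values. Many more genes were called in the real input data, so the shares are not the sensitivity of those comparisons. In the cold comparison of input it recovered 40% of genes changed by a log2 of 1, 80% at 2, 96% at 3 and 94% at 4. In the knockout comparison of input it recovered 36%, 78%, 96% and 98%, and in m6A enrichment of WT RT 68%, 96%, 100% and 100%. For the cold change of m6A enrichment the shares were 46%, 74%, 90% and 94%, for its knockout change 32%, 86%, 98% and 96%, for footprints 16%, 70%, 82% and 94%, and for translational efficiency 0%, 48%, 78% and 82%. Between 0 and 13 unchanged genes were called.

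The lists, the models, the naming rule and the following alternatives were chosen before the data were examined: other pseudocounts, no filter or a stricter one, median-ratio and quantile scaling, a robust fit, all 16 libraries in 1 fit, footprints alone, a minimum fold change, a block for the replicate number with or without the condition, and leaving out each library in turn. Further alternatives were chosen after seeing the data: voom on recovered reads, median-ratio factors applied to RPKM, scaling to reads outside mitochondrial mRNAs, Lars2 and Gm20594, and pairings of these with the block. Splits of the libraries at random were not counted, since groups hold 2 libraries. Positions of m6A within transcripts were not analysed, because the deposited values are per gene.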

Results

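A total of 16 libraries of mouse adipose tissue were compared, with 2 libraries in each of 8 groups: input RNA and anti-m6A precipitates from WT RT, WT cold and cKO cold mice, and ribosome footprints from WT cold and cKO cold mice. METTL3 is the catalytic subunit of the enzyme that writes m6A on mRNA, and the series concerns its part in the browning of fat in the cold through Klf9 mRNA. Recovered reads ran from 3895031 to 8673393 in the input libraries, from 4883129 to 6426541 in the m6A libraries, and from at least 1676208 to 2461267 in the footprint libraries. Values are the deposited RPKM, fold changes are those of RPKM + 1, and errors are standard errors with n = 2 libraries per group.

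Thermogenic genes rose in the input RNA of WT mice kept in the cold, the comparison that asks how the tissue's RNA responded to cold. Ucp1, the uncoupling protein that lets mitochondria release heat, stood at 2.13 and 9.91 RPKM in the WT RT libraries and at 854 and 639 RPKM in the WT cold libraries, a log2 fold change of 6.98 ± 0.92 (limma adjusted p = 0.00108). Fabp3, which carries fatty acids within cells, rose by 6.87 ± 0.74. Elovl3, an enzyme that lengthens fatty acids, rose by 5.92 ± 0.33. Cyp2b10, a cytochrome P450, rose by 4.14 ± 0.52. Tmem38b, an intracellular cation channel, rose by 3.67 ± 0.38 in input, but its m6A reads went from 367 in WT RT to 228 in WT cold. Its input was also high against WT RT in the libraries labelled cKO, as given below. Dio2, which activates thyroid hormone, rose by 3.17 ± 0.20, Cidea, a lipid droplet protein of brown and beige fat, by 1.95 ± 0.26, and Ppargc1a, a coactivator of mitochondrial genes, by 1.66 ± 0.26. Pparg, the main transcription factor of adipocytes, rose by 0.84 ± 0.17 (limma adjusted p = 0.00542). Prdm16, a regulator of brown fat genes, did not pass the test (-0.52 ± 0.31, limma adjusted p = 0.186). Klf9 stood at 25.1 and 26.1 RPKM in WT RT and at 28.8 and 48.0 RPKM in WT cold, a log2 fold change of 0.52 ± 0.24 that did not pass (limma adjusted p = 0.101). It passed with median-ratio scaling (1.18, limma adjusted p = 0.013). It also passed with quantile scaling, with median-ratio factors on RPKM and with scaling to reads outside mitochondrial mRNAs, Lars2 and Gm20594. The Klf9 call thus depended on the scaling. Without WT cold input replicate 1 its log2 fold change was 0.88. Mettl3 fell by 1.03 ± 0.30 (limma adjusted p = 0.0231), but its log2 fold change was -0.37 with median-ratio scaling (limma adjusted p = 0.33). The Mettl3 call was also lost without WT RT input replicate 1 or 2 or WT cold input replicate 2 (limma adjusted p = 0.075 to 0.129).

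**Figure D1:**
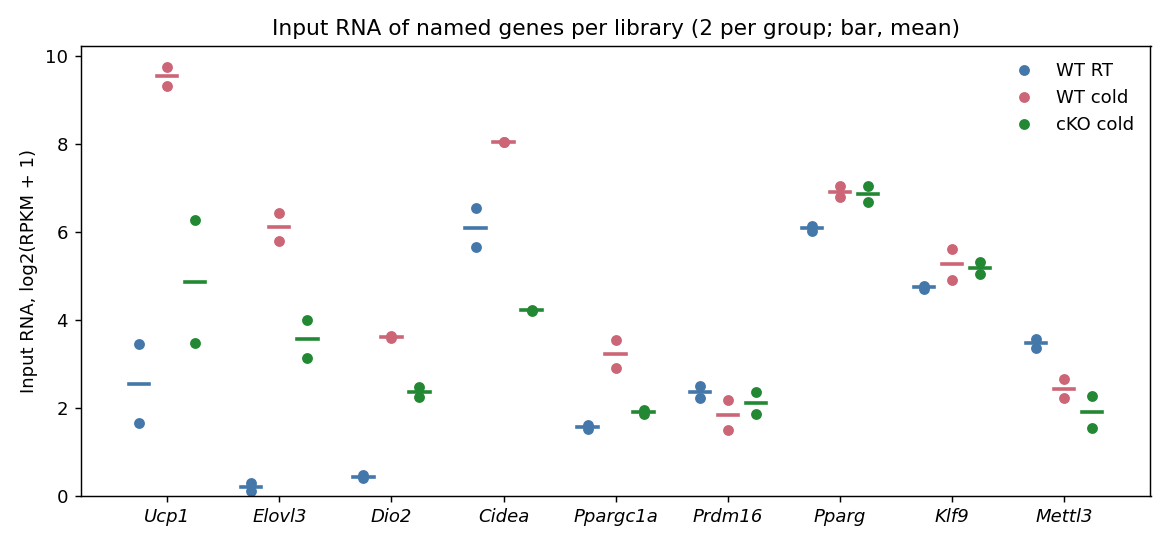
Log2(RPKM + 1) of 9 genes in each of the 6 input libraries, by group (points, libraries; bars, group means of 2 libraries). Ucp1 stood at 854 and 639 RPKM in WT cold, and its mean stood at 43.2 RPKM in the libraries labelled cKO.

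Of 12667 genes tested, 826 were higher and 6488 lower in WT cold than in WT RT (limma, 7985 at an unadjusted p under 0.05). The median gene stood at a log2 fold change of -0.67, and directions of gene groups are therefore given relative to this median. Median-ratio scaling, which sets the median gene to no change, called 2412 genes higher and 2408 lower, quantile scaling 2652 and 2357, and scaling to reads outside mitochondrial mRNAs, Lars2 and Gm20594 1149 and 4879. Without WT RT input replicate 1 the calls numbered 3419, and without replicate 2 of that group 3956. Temperature was confounded with the series of library codes.

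Genes of heat production and fuel use moved together in the cold. Of 29 thermogenic and beige markers tested, 23 were higher and 4 lower, with a list median 2.45 above that of all genes. Fatty acid oxidation (23 higher and 1 lower of 25), the TCA cycle (16 and 0 of 18), complex I subunits (30 and 0 of 34), complex II to V subunits (33 and 2 of 39), mitochondrial DNA-encoded mRNAs (10 and 0 of 10), de novo lipogenesis (17 and 0 of 20) and lipolysis and fatty acid uptake (12 and 0 of 17) moved the same way. Cpt1b, which lets fatty acids into mitochondria, rose by 3.40 ± 0.26, Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, by 1.99 ± 0.12, Idh3a of the TCA cycle by 1.95 ± 0.14, and Elovl6 of lipogenesis by 2.26 ± 0.21. Gk, which lets adipocytes reuse glycerol, rose by 3.23 ± 0.33. With adjustment over the list alone, complex II to V subunits gave 34 higher and 2 lower and lipogenesis 18 higher, and the other 6 of these lists gave the counts above. All 8 lists passed limma's camera with its preset correlation (largest adjusted p = 5.39e-14), but none with an estimated correlation (adjusted p = 0.106 to 0.111). With quantile scaling, 2 of the 10 mitochondrial DNA-encoded mRNAs stayed higher.

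Other groups were lower in the cold. All 18 T and B cell markers tested fell, with a list median at -4.55 from that of all genes (camera adjusted p = 1.45e-10, adjusted p = 0.107 with an estimated correlation). Cd79a, a chain of the B cell receptor, was at least 1440-fold lower in WT cold, where it had no reads, against a floor of 3 reads over the group. Glycam1, made by the high endothelial venules of lymph nodes, was at least 747-fold lower and Fcmr, the receptor for IgM, at least 724-fold. Ccl21a, the chemokine that draws lymphocytes into lymph nodes, (-7.40 ± 0.29) and Cd79b, the partner of Cd79a (-6.64 ± 0.27), fell too. Of 46 cytosolic ribosomal proteins tested, 45 were lower (41 with median-ratio scaling), among them Rplp0 at -2.01 ± 0.11, with a list median at -0.98 from that of all genes (camera adjusted p = 7.03e-12, adjusted p = 0.183 with an estimated correlation). Neutrophil and mast cell markers (12 lower of 15, adjusted p = 0.163 with an estimated correlation), interferon-stimulated genes (19 of 22; 0.677) and the cell cycle (17 of 19; 0.583) also passed camera downwards, with 9, 9 and 7 members lower under median-ratio scaling. Isg15, an antiviral ubiquitin-like protein, fell by 2.11 ± 0.23 and Mcm6, a helicase of DNA replication, by 2.35 ± 0.25. Members of the macrophage markers (13 lower and 1 higher of 19; 7 and 2 with median-ratio scaling), fibroblast and preadipocyte markers (13 of 20; 5), immediate early genes (12 of 20; 10) and smooth muscle and pericyte markers (8 of 10; 1 lower and 2 higher) were lower too, but these 4 lists did not pass camera. Over the list alone, 14 macrophage markers were lower and 1 higher, all 19 cell cycle genes were lower, and the other lists of this paragraph kept their counts. T and B cell markers held 0.2353% and 0.2169% of reads in the WT RT inputs and 0.0006% in both WT cold inputs. Falls of genes that lymphocytes also express therefore do not separate a change within cells from a smaller share of lymphocyte RNA.

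Of the m6A writers, erasers and readers, 18 of 23 were lower, among them the cap methyltransferase Pcif1 (-1.45 ± 0.18), but the list median lay only at -0.14 from that of all genes (camera adjusted p = 0.156) and median-ratio scaling left 3 lower and 2 higher. KLF transcription factors gave 6 lower of 12, among them Klf13 (-1.61 ± 0.13), with a list median of -0.63 that turned to 0.03 with median-ratio scaling (camera adjusted p = 0.713). Endothelial markers (7 lower of 16; 3 higher and 1 lower with median-ratio scaling), insulin signalling (2 higher and 7 lower of 19; 5 and 2), beta-adrenergic and cAMP signalling (4 and 6 of 18; 7 and 4), Schwann cell and nerve markers (1 higher of 9) and skeletal muscle markers (1 lower of 17) did not pass camera. Those that passed upwards were the adipocyte markers (7 higher and 4 lower of 22, adjusted p = 0.108 with an estimated correlation), the circadian clock (1 higher of 19; 0.107), heat shock proteins (3 and 3 of 13; 0.27), the ATF4 response (3 and 5 of 19; 0.183), glucocorticoid-induced genes (1 and 1 of 16; 0.596), UCP1-independent heat (2 higher of 9; 0.166) and red blood cell markers (2 higher of 7; 0.446). Adjusted over the list alone, UCP1-independent heat, the circadian clock, red blood cell and skeletal muscle markers gave 0 calls, insulin signalling 1 higher and 7 lower, heat shock proteins 3 and 1, and glucocorticoid-induced genes 1 higher. For the adipocyte, circadian, ATF4 and glucocorticoid lists the median change was below 0 although camera, which compares a list with all other genes, pointed up, and for UCP1-independent heat the median was 0.04 and the mean -0.34. Skeletal muscle markers had a median of -2.25 where camera pointed up (adjusted p = 0.603). Acta1, the actin of skeletal muscle, stood at 105 and 4.3 RPKM in the WT RT inputs and at 0.718 and 5.59 in the WT cold inputs. For this gene WT RT input replicate 1 thus stood apart. Of the mammary and skin epithelium markers 2 were tested and 0 were called, and of the male reproductive tract markers 0 were tested.

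**Figure D2:**
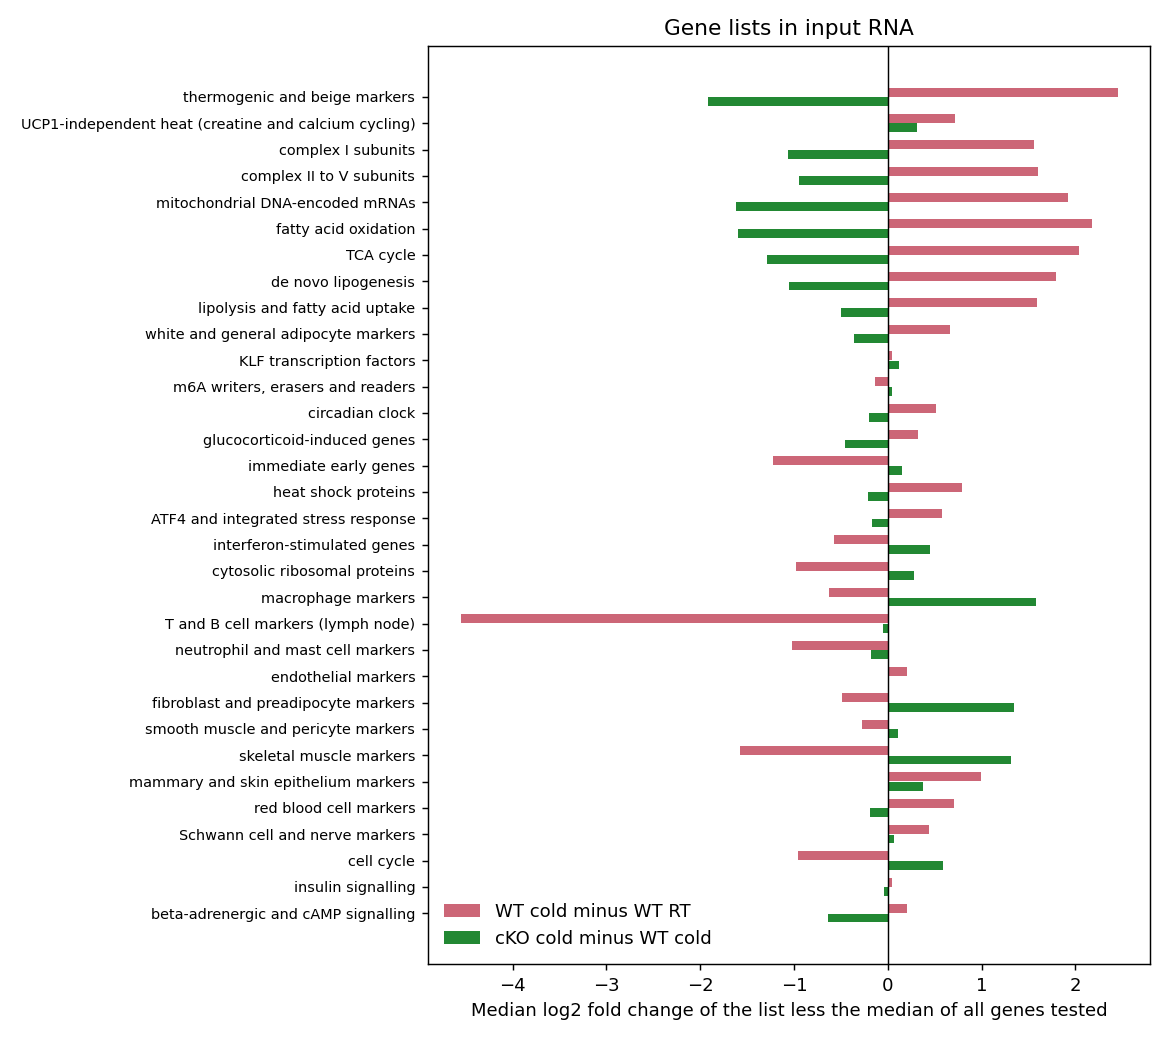
Median log2 fold change of 32 gene lists less the median of all genes, in input RNA, for WT cold less WT RT and cKO cold less WT cold (bars, list medians). The thermogenic list lay at 2.45 from all genes in the cold and at -1.92 in the libraries labelled cKO. Before the all-gene median is taken off, the KLF, endothelial, insulin, beta-adrenergic, circadian, glucocorticoid, ATF4, Schwann cell and adipocyte medians of the cold comparison lie below 0.

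Libraries labelled cKO were compared with WT cold within 1 series of library codes, which asks what loss of Mettl3 from adipocytes changed in the cold. Mettl3 itself stood at 5.24 and 3.66 RPKM in the WT cold inputs and at 3.83 and 1.90 RPKM in the inputs labelled cKO, at 4.23 and 2.69 against 5.37 and 2.33 RPKM in the m6A libraries, and at 4.60 and 4.82 against 8.99 and 5.22 RPKM in the footprints. The input difference was -0.53 ± 0.30 and did not pass (limma adjusted p = 0.215), and the footprint RPKM lay the other way, so Mettl3 RNA did not separate the genotypes in these libraries. RNA of other cell types without Cre is part of the tissue, and deposited values per gene do not show a deleted exon.

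Thermogenic genes were lower in the inputs labelled cKO than in WT cold. Fabp3 fell by 4.71 ± 0.74 and Ucp1, with a mean of 43.2 RPKM (SD 46.8), by 4.66 ± 0.92 (limma adjusted p = 0.0148), a call lost without WT cold input replicate 2 (-4.87 ± 1.23, limma adjusted p = 0.0534). Cidea fell by 3.83 ± 0.26 (limma adjusted p = 0.0025), Elovl3 by 2.54 ± 0.33, Dio2 by 1.25 ± 0.20 and Ppargc1a by 1.32 ± 0.26. The Elovl3 call was lost with all 16 libraries in 1 fit (limma adjusted p = 0.0551), and that of Ppargc1a without cKO input replicate 1 (0.0583). Pdk4, which holds back glucose oxidation, fell by 3.72 ± 0.57, H2-Q10, a class Ib histocompatibility gene, by 3.49 ± 0.18, Cpt1b by 3.43 ± 0.26, and Letmd1, a mitochondrial protein of brown fat, by 2.03 ± 0.18. Adrb3, the adrenergic receptor that starts heat production in adipocytes, fell by 1.36 ± 0.15. Klf9, at 38.6 and 32.0 RPKM, did not pass (-0.08 ± 0.24, limma adjusted p = 0.822), nor did Pparg (-0.06 ± 0.17, limma adjusted p = 0.812) or Prdm16 (0.27 ± 0.31, limma adjusted p = 0.532).

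Most macrophage markers were higher in the inputs labelled cKO, as counted below. The genes of the next sentence are not members of that list. Adam8, a membrane protease, rose by 3.87 ± 0.29, Mmp12, the macrophage elastase, by 3.86 ± 0.54, Ccl2, which draws monocytes, by 3.82 ± 0.35, Fas, a death receptor, by 3.65 ± 0.24 and Atp6v0d2, a proton pump subunit, by 3.52 ± 0.59. Cd68, a lysosomal protein of macrophages, rose from 12.9 and 16.9 to 175 and 139 RPKM (3.31 ± 0.18, limma adjusted p = 0.0019) and Trem2, a lipid receptor of macrophages, by 3.48 ± 0.42. Of 19 macrophage markers 15 were higher (14 with median-ratio scaling; camera adjusted p = 6.44e-06, adjusted p = 0.413 with an estimated correlation). Of 20 fibroblast and preadipocyte markers 19 were higher (7 with median-ratio scaling; camera adjusted p = 4.34e-05, adjusted p = 0.595 with an estimated correlation), among them Col6a1, a collagen, by 2.18 ± 0.23. Cytosolic ribosomal proteins gave 38 higher of 46 (5 with median-ratio scaling; camera adjusted p = 2.14e-08, adjusted p = 0.331 with an estimated correlation), interferon-stimulated genes 10 of 22 (1; 0.786) and the cell cycle 8 of 19 (5; 0.744). Neutrophil and mast cell markers gave 6 higher of 15 (3 with median-ratio scaling), among them the mast cell protease Cma1 (2.60 ± 0.33), m6A writers, erasers and readers 6 of 23 (2), among them the readers Ythdf1 (1.12 ± 0.16) and Ythdf2 (1.21 ± 0.18), KLF transcription factors 5 of 12 (2), and T and B cell markers 3 of 18 (0). These 4 lists did not pass camera. Adjusted over the list alone, 16 macrophage, 19 fibroblast, 41 ribosomal, 11 interferon, 9 cell cycle, 6 neutrophil and mast cell, 9 m6A, 5 KLF and 2 T and B cell genes were higher.

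Of the fuel-use lists, thermogenic and beige markers gave 22 lower and 1 higher of 29, fatty acid oxidation 19 and 1 of 25, the TCA cycle 15 and 0 of 18, complex I 25 and 0 of 34, complexes II to V 22 and 1 of 39, mitochondrial DNA-encoded mRNAs 10 and 0 of 10 (2 lower with quantile scaling), and lipogenesis 12 and 1 of 20. Adjusted over the list alone, 22, 21, 15, 28, 27, 10 and 14 members were lower. All 7 passed camera (largest adjusted p = 2.73e-15), but with an estimated correlation none did (adjusted p = 0.0663 for the thermogenic list and 0.121 to 0.185 for the others). Hadhb of fatty acid oxidation fell by 1.42 ± 0.12 and Pnpla2, the first lipase of lipolysis, by 1.39 ± 0.21. Lipolysis and fatty acid uptake (3 lower and 1 higher of 17, adjusted p = 0.121 with an estimated correlation) beta-adrenergic and cAMP signalling (2 and 2 of 18; 0.121), adipocyte markers (3 and 3 of 22; 0.188), the circadian clock (1 lower of 19; 0.188) and glucocorticoid-induced genes (1 and 1 of 16; 0.595) also passed camera downwards.

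In all, 2992 genes were higher and 370 lower in the inputs labelled cKO (limma, 5475 at an unadjusted p under 0.05). The median gene stood at a log2 fold change of 0.40, and median-ratio scaling called 748 higher and 784 lower, quantile scaling 752 and 638, and scaling to reads outside mitochondrial mRNAs, Lars2 and Gm20594 1922 and 458. Without cKO input replicate 1 the calls numbered 1729, and without WT cold input replicate 2 they numbered 1895.

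Changes in the libraries labelled cKO ran opposite to those of the cold. Of genes called in the cold comparison, 90.3% had a change of opposite sign. Because both comparisons share the WT cold libraries, 100 simulations with no effect gave 88.9%. That share covers only the simulated genes with the largest cold change for their error. The observed share covers all called genes and includes the opposite shifts of the median gene (-0.67 and 0.40). The shares are therefore not directly comparable. The log2 fold changes correlated across 12667 genes at -0.485 (simulated, -0.500), and their covariance was -0.296 against a simulated -0.0337, a difference of -0.263. With the WT cold libraries split, so that no library was shared, the covariance was -0.230 and -0.247. A total of 283 genes were called higher in the cold and lower with the cKO label, where independent lists would share 24.1, and 2208 were lower and then higher, against 1532; with median-ratio scaling the counts were 654 against 149.3 and 359 against 142.2. Neither the simulated values nor the independent counts leave only a shared effect. The lists share the WT cold libraries, so their overlap can exceed the independent counts without any effect, and it was not simulated. Genes are not independent replicates.

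In the direct comparison of cKO cold with WT RT inputs, Elovl3 (3.38 ± 0.33, limma adjusted p = 0.00086) and Dio2 (1.92 ± 0.20, limma adjusted p = 0.0011) were higher than in WT RT, Cidea was lower (-1.88 ± 0.26, limma adjusted p = 0.0029), and Ucp1 (2.32 ± 0.92, limma adjusted p = 0.095) and Ppargc1a (0.34, limma adjusted p = 0.34) did not pass. Mettl3 was lower than in WT RT (-1.55 ± 0.30, limma adjusted p = 0.0091). Tmem38b (4.25 ± 0.38), Mogat2, which makes diacylglycerol (4.09 ± 0.25), and Oxtr, the oxytocin receptor (3.67 ± 0.37), were among the 5 highest. A total of 1062 genes were higher and 3130 lower (limma, 5743 at an unadjusted p under 0.05; 1956 and 2019 with median-ratio scaling). Of 46 cytosolic ribosomal proteins 44 were lower and all 18 T and B cell markers were lower, with the same counts adjusted over the list alone; both lists passed camera, but not with an estimated correlation (adjusted p = 0.395 and 0.316). This comparison also spans both series of library codes, and the share of lymphocyte RNA differed between its groups.

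Anti-m6A enrichment of each gene was measured against the input of the same condition. Both values are shares of the reads of their own libraries, so enrichment compares genes with one another and not total m6A between conditions. In WT RT, Prpf38b, a splicing factor (2.84 ± 0.18), Basp1, a membrane signalling protein (2.84 ± 0.34), Gpatch4 (2.65 ± 0.32) and Hmgn5, a nucleosome-binding protein (2.60 ± 0.15), were among the most enriched. Prdx1, a peroxidase (-3.92 ± 0.16), the ribosomal genes Rpl30 (-3.62 ± 0.30) and Rps21 (-3.23 ± 0.21), the olfactory receptor gene Olfr774 (-3.44 ± 0.35) and Cox6c of the respiratory chain (-3.40 ± 0.21) were the most depleted. Of 46 cytosolic ribosomal proteins, 44 were depleted (camera adjusted p = 6.08e-17, adjusted p = 0.656 with an estimated correlation; 45 adjusted over the list alone), as were 18 of 18 TCA cycle genes (0.656; 18) and 19 of 25 fatty acid oxidation genes (0.656; 20). Immediate early genes gave 6 enriched of 20 (adjusted p = 0.703 with an estimated correlation; 6 adjusted over the list alone; 15 with pairs as blocks) and KLF transcription factors 3 of 13 (0.656; 3; 6 with pairs as blocks). Hmgn5 (3.89 ± 0.15) and Prpf38b (3.30 ± 0.18) led again in WT cold, and also in cKO cold (4.07 ± 0.15 and 3.80 ± 0.18).

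Klf9 was enriched by 0.77 ± 0.30 in WT RT (limma adjusted p = 0.056, 2e-04 with pairs as blocks), by 0.57 ± 0.30 in WT cold (limma adjusted p = 0.167, 0.0013 with pairs as blocks, and 0.0327 without m6A WT cold replicate 1) and by 0.08 ± 0.30 in cKO cold (limma adjusted p = 0.857, 0.52 with pairs as blocks). Whether these differ is tested by the interactions below. Pparg was depleted in WT RT (-0.73 ± 0.16, limma adjusted p = 0.00414) and cKO cold (-1.31 ± 0.16, limma adjusted p = 0.000145). In WT cold its value of -0.54 ± 0.16 (limma adjusted p = 0.0247) passed, but not without WT cold input replicate 1 (limma adjusted p = 0.138) or WT cold m6A replicate 1 (0.0621) or 2 (0.104). In WT RT 2088 genes were enriched and 4524 depleted (limma, 7397 at an unadjusted p under 0.05), in WT cold 1792 and 3341 (6174), and in cKO cold 1490 and 4602 (6935). With pairs as blocks the counts were 2776 and 5304, 2528 and 4171, and 2106 and 5518. With median-ratio scaling they were 2165 and 4504, 1521 and 3912, and 1753 and 4212. Quantile scaling gave 2142 and 4433, 1560 and 3889, and 1765 and 4202. Whether WT cold or cKO cold had more enriched genes therefore depended on the scaling.

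Ribosomal protein mRNAs lay above other genes in the cold change of m6A enrichment by camera with its preset correlation. The list median of the change was 0.67, or 0.56 above that of all genes (camera adjusted p = 2.11e-20, adjusted p = 0.626 with an estimated correlation), with 0 of 46 members called over all genes, 26 adjusted over the list alone, and 23 and 37 with pairs as blocks. Mitochondrial DNA-encoded mRNAs (0 of 10 called; 4 with pairs as blocks, adjusted p = 0.953 with an estimated correlation) and the TCA cycle (0 of 18; 2; 0.953) also passed camera upwards, and no list passed fry without pairs as blocks. T and B cell markers held 0.2152% and 0.2087% of reads in the WT RT m6A libraries but 0.0004% and 0.0007% in the WT cold ones, as in the inputs, so the share of lymphocyte RNA differed between the conditions compared. Klf9 did not pass (-0.20 ± 0.43, limma adjusted p = 0.929), nor did Mettl3 (0.12 ± 0.48, limma adjusted p = 0.97). By limma 3 genes passed upwards and 5 downwards (1486 at an unadjusted p under 0.05), several with few or no reads in a condition, with 222 and 48 when pairs were blocks (85 and 54 with median-ratio scaling as well), 28 and 13 with quantile scaling, and 0 by voom. The 8 calls fell to 0 without any 1 of the WT RT input, WT RT m6A or WT cold m6A libraries and to 3 without WT cold input replicate 2, and the 270 paired calls to between 0 and 2 without any 1 pair.

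Adipocyte markers lay below other genes in the change of m6A enrichment with the cKO label by camera with its preset correlation. The comparison asks whether m6A of some genes changed against that of others with the cKO label. A fall of m6A shared by most genes would not show in it, because enrichment is relative within each library. The median change over 22 white and general adipocyte markers was -0.57, against -0.14 over all genes (camera adjusted p = 0.00902, adjusted p = 0.963 with an estimated correlation). Over all genes 0 of these markers passed, and adjusted over the list alone 5 were lower; with pairs as blocks the counts were 9 lower, and 13 lower and 1 higher (camera adjusted p = 5.33e-08, adjusted p = 0.642 with an estimated correlation). Adipoq, the hormone adiponectin, stood at 794 and 790 RPKM in the WT cold m6A libraries and at 518 and 482 in those labelled cKO, while its input stood at 498 and 471 and at 621 and 724; its enrichment change of -1.13 ± 0.18 did not pass (limma adjusted p = 0.0885) but did with pairs as blocks (0.0093). The same held for Pparg (-0.78 ± 0.23, limma adjusted p = 0.266; 0.014 with pairs as blocks), Klb, the FGF21 co-receptor (-1.87 ± 0.29; 0.0064), Rab9, which returns proteins from endosomes (-1.32 ± 0.16; 0.0084), Lipt1, which attaches lipoic acid to enzymes (-1.88 ± 0.29; 0.0085), and Cpt2 of fatty acid oxidation (-1.35 ± 0.23; 0.0093). De novo lipogenesis gave 0 members called of 20 and 4 lower with pairs as blocks (9 adjusted over the list alone), and passed camera with pairs as blocks alone (adjusted p = 4.59e-05; 0.642 with an estimated correlation). So did fatty acid oxidation, downwards (3 lower of 25; 0.0425; 0.642). Mitochondrial DNA-encoded mRNAs passed camera upwards with 0 of 10 members called (adjusted p = 0.0282, or 0.00238 with pairs as blocks; 0.963 and 0.642 with an estimated correlation). Klf9 did not pass (-0.49 ± 0.43, limma adjusted p = 0.78; 0.099 with pairs as blocks), nor did Mettl3 (0.59 ± 0.48, limma adjusted p = 0.753). By limma 0 genes were called (1311 at an unadjusted p under 0.05), by voom 0, with median-ratio scaling 1, and with pairs as blocks 8 higher and 397 lower. Median-ratio scaling as well as pairs gave 6 and 101. The 405 paired calls fell to 0 without either WT cold pair, to 298 without cKO pair 1 and to 118 without cKO pair 2. The unpaired count was 6 without WT cold input replicate 1.

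**Figure D3:**
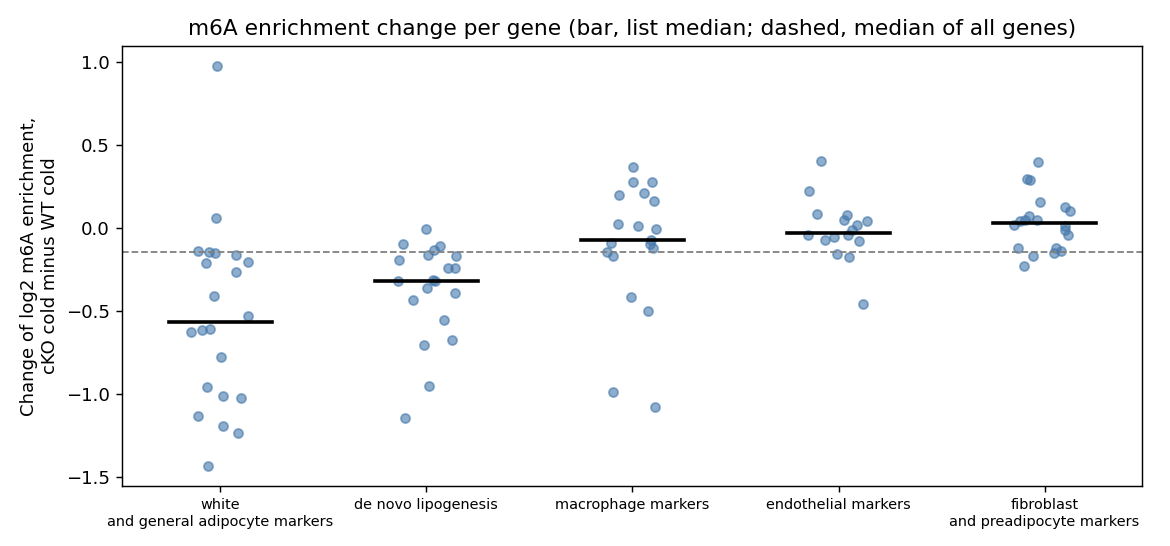
Change of log2 m6A enrichment, cKO cold less WT cold, for each gene of 5 lists (points, genes; bars, list medians; dashed line, median of all genes at -0.14). The adipocyte median stood at -0.57 and the macrophage, endothelial and fibroblast medians at -0.07, -0.03 and 0.03.

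Genes with m6A enrichment in WT RT were followed as a set, since the libraries that define it do not enter the fold changes between WT cold and cKO cold. In the input and m6A fits they do help to set the variance. The set of 850 genes changed in enrichment by a median of -0.17 in the libraries labelled cKO, against -0.14 for other genes (n = 850 genes, limma's camera p = 0.197, or 0.132 with pairs as blocks). With pairs as blocks 1 gene of the set was higher and 76 lower, against 8 and 397 of all 13062 genes tested. Without the blocks 0 genes of the set were called. In input RNA 308 of its 821 tested genes were higher and 9 lower, with a median of 0.63 against 0.39 (camera p = 0.00013; p = 0.103 with an estimated correlation). In footprints 57 were higher and 5 lower, with a median of 0.60 against 0.41 (camera p = 0.0055; p = 0.231 with an estimated correlation). Translational efficiency of the set did not differ detectably from that of other genes (-0.08 against 0.00, n = 808 genes, limma's camera p = 0.231), with the limits of this ratio given below.

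Thermogenic mRNAs were also lower in ribosome footprints labelled cKO, the comparison of mRNA held on ribosomes in the cold. Cidea fell by 3.94 ± 0.30 (limma adjusted p = 0.00186), and Ucp1, at 3790 and 2490 RPKM in WT cold and 149 and 88.4 in the libraries labelled cKO, fell likewise (-4.73 ± 0.74, limma adjusted p = 0.0154). The Ucp1 call was lost without WT cold footprint replicate 2 (limma adjusted p = 0.0661) or cKO footprint replicate 1 (0.0553). Slc27a2, which activates fatty acids, fell by 4.38 ± 0.52, Acot11, a thioesterase induced in brown fat, by 4.30 ± 0.39, Cpt1b by 3.68 ± 0.31 and Acsl5, an acyl-CoA synthetase, by 3.71 ± 0.36. Fabp3 (-4.40 ± 0.85) passed, but not without WT cold footprint replicate 1 (limma adjusted p = 0.0662) or 2 (0.0905) or cKO footprint replicate 2. Pdk4 (-4.17 ± 0.73) passed, but not without WT cold footprint replicate 2 (0.0959) or cKO footprint replicate 1 (0.0551) or 2 (0.0544). Dio2 (-1.37 ± 0.40, limma adjusted p = 0.0708; 0.0275 without WT cold footprint replicate 1) and Elovl3 (-3.37 ± 1.06, limma adjusted p = 0.0811; 0.0089 with pairs as blocks and 0.022 without cKO footprint replicate 2) did not pass. Klf9 (0.18 ± 0.38, limma adjusted p = 0.786), Pparg (-0.10 ± 0.31, limma adjusted p = 0.853) and Mettl3 (0.47 ± 0.37, limma adjusted p = 0.411) did not pass either.

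Thermogenic and beige markers (16 lower of 30, median -2.33), fatty acid oxidation (16 of 25) and complex I subunits (9 of 34, median -0.72) were lower in the footprints and passed camera with an estimated correlation as well (adjusted p = 0.00621, 0.0218 and 0.0442, or 0.151 for each with pairs as blocks). Adjusted over the list alone, 21, 20 and 22 of these were lower and 1, 1 and 0 higher. Complexes II to V (8 lower of 39, adjusted p = 0.0966 with an estimated correlation), the TCA cycle (10 of 18; 0.131), mitochondrial DNA-encoded mRNAs (4 of 10; 0.131) and lipogenesis (3 of 20; 0.259) passed only with the preset correlation. Over their own lists, 21, 14, 9 and 6 of these were lower and 2, 0, 0 and 1 higher. Fibroblast and preadipocyte markers gave 6 higher of 20 (17 adjusted over the list alone; 3 with median-ratio scaling; 15 with pairs as blocks, adjusted p = 0.405 with an estimated correlation) and macrophage markers 7 of 19 (13; 1; 15; 0.405). Mogat2 rose by 4.24 ± 0.36 (limma adjusted p = 0.00222). Smim1, Krtap15 and Krtap8-1 were listed at 0 in both WT cold libraries, so no fold is given. Of 18 T and B cell markers 0 were called.

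In all, 716 genes were higher and 196 lower in footprints labelled cKO (limma, 3878 at an unadjusted p under 0.05), with a median gene at 0.42. Median-ratio scaling called 127 higher and 359 lower, quantile scaling 137 and 297, and scaling to reads outside mitochondrial mRNAs, Lars2 and Gm20594 336 and 225. The calls numbered 93 without WT cold footprint replicate 2 and 94 without cKO footprint replicate 1.

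The ratio of footprints over input of the thermogenic genes, used here as translational efficiency, did not change detectably with the cKO label. Ucp1 (-0.07 ± 1.05), Cidea (-0.11 ± 0.42), Klf9 (0.25 ± 0.54) and Mettl3 (0.99 ± 0.52) each had a limma adjusted p of 1. Cd68 (-1.85 ± 0.36, limma adjusted p = 1; 0.43 with pairs as blocks) had the smallest p among the 19 macrophage markers, whose median change of -0.61 passed camera (adjusted p = 0.000152), but not with an estimated correlation (adjusted p = 0.933). Ratios of immune genes are not read as translation here, because T and B cell markers stood at a log2 ratio of footprints over input of 4.53 in WT cold and 4.77 in cKO cold. Neutrophil and mast cell markers stood at 2.62 and 3.01. Acta1 stood at 1.23 and 40.1 RPKM in the inputs labelled cKO but at 82.6 and 2.01 in the footprints. Input and footprints may thus hold unlike tissue, so ratios of other genes, thermogenic genes included, need not measure translation alone. Fatty acid oxidation genes had a median of -0.30 (camera adjusted p = 0.00318, adjusted p = 0.933 with an estimated correlation). By limma 0 genes were called (459 at an unadjusted p under 0.05, 638 expected by chance), with pairs as blocks 0, by voom 0, and by voom with pairs as blocks 4. Changes of a log2 of 1 were recovered for 0% of genes in the simulation, so changes of that size were not detectable here.

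T and B cell markers took very different shares of the reads across assays of the same condition. They held 0.2353% and 0.2169% of input reads in WT RT, 0.0006% in both WT cold inputs, and 0.0039% and 0.0021% in the inputs labelled cKO, and the m6A libraries lay close to their inputs. In the footprints they held 0.0590% and 0.0431% in WT cold and 0.123% and 0.0416% in those labelled cKO. Glycam1 stood at 252 and 291 RPKM in the WT RT inputs, at 0 in every cold input and m6A library, and at 160 and 176 RPKM in the WT cold footprints. Cd79a stood at 112 and 71.5 RPKM in the WT cold footprints against 0 in the WT cold inputs.

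**Figure D4:**
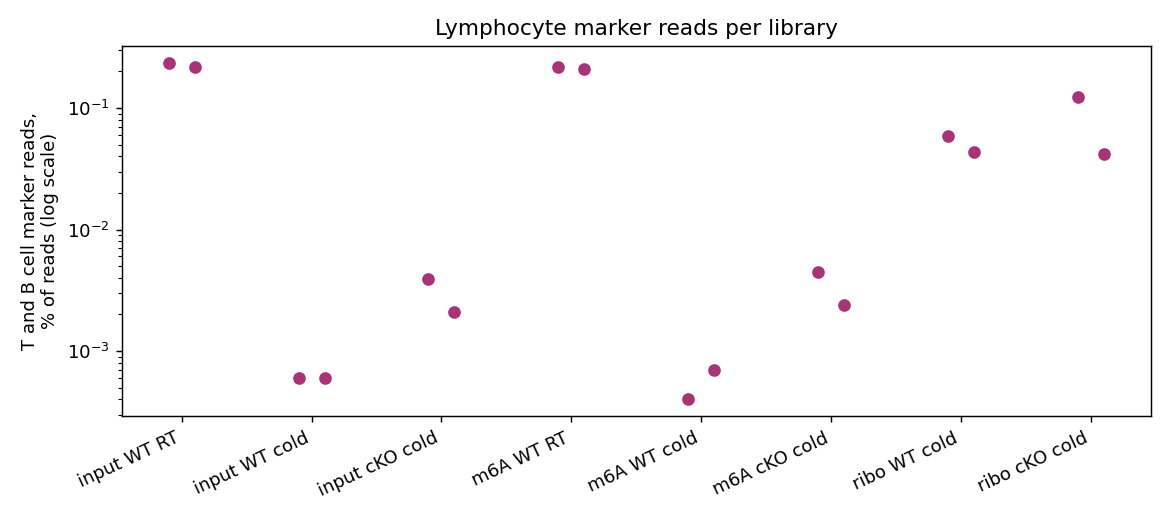
Percent of reads on T and B cell markers in each of the 16 libraries, on a log axis (points, libraries). The WT RT inputs hold 0.2353% and 0.2169%, the WT cold inputs 0.0006%, and the WT cold footprints 0.0590% and 0.0431%.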

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

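The 8 genes below passed a test of the difference in m6A enrichment between WT cold and WT RT, which was planned, as was the fit with pairs as blocks. Tmem38b changed by -4.49 ± 0.50 (limma adjusted p = 0.0268, or 0.00691 with pairs as blocks), with enrichment of 0.21 in WT RT and -4.28 in WT cold. For Rnf225 the change was -2.83 ± 0.32 (0.0268, or 0.0225). Klkb1 changed by -2.18 ± 0.29 (0.0432, or 0.0229), and Cideb by -1.89 ± 0.26 (0.0474, or 0.0226). Both had 3 or fewer m6A reads in each condition. Cideb had 2 input reads and 1 m6A read in the WT RT libraries, so its enrichment there was hardly measured. Olfr729 (-1.80 ± 0.24; 0.0432, or 0.0226) had no reads in any WT RT library, so its enrichment there was not measured and the value shows no difference in enrichment. H2bc12, a histone gene (2.88 ± 0.38; 0.0432, or 0.0232), had no reads in the WT cold inputs and 1 in the WT cold m6A libraries, and the same holds for it. Plac8 changed by 2.85 ± 0.35 (0.0432, or 0.0226). Dsc3, a protein of desmosomes (1.59 ± 0.22; 0.0432, or 0.0271), had no reads in any WT cold library, so its value only turns the sign of that in WT RT. All 8 calls were lost when any 1 of the WT RT input, WT RT m6A or WT cold m6A libraries was left out.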

How the results depend on the processing

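Among 415 named-gene results, 0 values that passed with or without an alternative changed sign, but 92 values of 34 results that passed in neither did, among them Prdm16 in cold input (-0.52, or 0.37 with quantile scaling). With median-ratio scaling 357 stayed on their side of the threshold, with quantile scaling 353, with no filter 363, with a pseudocount of 0.1 391, and by voom 379. Footprints alone kept 34 and lost 42, and leaving out WT cold footprint replicate 1 or 2 or cKO footprint replicate 1 or 2 kept 72, 50, 46 and 65 and lost 19, 44, 45 and 23. With pairs as blocks 166 stayed, 41 calls were gained and 14 lost. The changed counts follow; where construction does not show it, the cause was not tested. For the cold change of m6A enrichment, 8 genes became 0 with a pseudocount of 0.1, 2 with 0.5, 16 with no filter, 2 with a mean RPKM of at least 5, 4 with median-ratio scaling, 41 with quantile scaling, 0 with the replicate number as block, 5 with all 16 libraries in 1 fit, 3 with a robust fit and 0 by voom. With pairs as blocks they became 270, or 139 with median-ratio scaling and 1185 by voom. For the knockout change of m6A enrichment, 0 genes became 2 with no filter and 1 with median-ratio scaling, quantile scaling, the replicate number as block, median-ratio factors, or scaling to reads outside mitochondrial mRNAs, Lars2 and Gm20594. With pairs as blocks they became 405, or 107 with median-ratio scaling and 1096 by voom. The 912 footprint calls became 572 with a pseudocount of 0.1, 372 with no filter, 486 with median-ratio scaling, 434 with quantile scaling, 479 with median-ratio factors, 561 with scaling outside mitochondrial mRNAs, Lars2 and Gm20594, 384 by voom, 1451 by voom with pairs as blocks, 3835 with all 16 libraries in 1 fit and 91 with footprints alone, where fewer libraries set the variance. The 0 calls for translational efficiency became 1 with quantile scaling, 3 with all 16 libraries in 1 fit and 4 by voom with pairs as blocks. In input RNA, 7314 cold calls became 4820 and 3362 knockout calls 1532 with median-ratio scaling, and the knockout calls 1390 with quantile scaling and 1620 with median-ratio factors. A minimum log2 fold change of 1, a stricter rule by construction, left 4383 and 1642 of these and 3282, 2301 and 2981 of the calls of m6A enrichment in WT RT, WT cold and cKO cold. When 1 library was left out, counts ran from 3419 (3956 without WT RT input replicate 2) to 7195 for cold, from 1729 (1895 without WT cold input replicate 2) to 3806 for knockout input, from 4741 to 4853, 3946 to 4536 and 4836 to 5452 for enrichment in WT RT, WT cold and cKO cold, from 0 to 7 (3 without WT cold input replicate 2) for the cold change of m6A enrichment, from 0 to 6 for its knockout change, from 93 (94 without cKO footprint replicate 1) to 889 for footprints, and at 0 throughout for translational efficiency. With an estimated correlation, the lists past camera fell from 20 to 0 for cold, 17 to 0 for knockout input, 8, 8 and 7 to 0 for enrichment in WT RT, WT cold and cKO cold, 3 to 0 and 2 to 0 for its cold and knockout changes, 15 to 3 for footprints and 2 to 0 for translational efficiency. By fry the enrichment lists were 14, 13 and 15, and those of the cold change, the knockout change and translational efficiency 0, 1 and 0. With pairs as blocks the last 3 were 5, 4 and 4 by camera and 2, 8 and 0 by fry. The m6A-enriched genes stood 0.246 above the others in knockout input, and with an estimated correlation this did not pass (p = 0.103). With 2 libraries per group, changes of translational efficiency near a log2 of 1 were beyond detection.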

Other observations

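Further members of the lists above changed in the cold in input RNA. Thy1, found on stromal progenitors and on T cells, fell by 3.72 ± 0.37 (limma adjusted p = 0.000408) and Dpp4, found on early preadipocytes and on T cells, by 1.82 ± 0.21 (limma adjusted p = 0.000655). Since all 18 T and B cell markers fell too, these values do not separate stroma from lymphocytes. Marco, a scavenger receptor of macrophages (-5.42 ± 0.37), and Plvap, of fenestrated endothelium (-1.99 ± 0.24), fell as well. Foxo1, a transcription factor held back by insulin, fell by 1.46 ± 0.16, while Slc2a4, the insulin-driven glucose transporter, rose by 1.06 ± 0.19. S100b, a secreted protein that guides nerve growth into fat, rose by 1.68 ± 0.34 in the cold and fell by 3.02 ± 0.38 in footprints labelled cKO (limma adjusted p = 0.00941). In inputs labelled cKO, Egr2, an early response gene, rose by 2.39 ± 0.29 and Mrc1, a mannose receptor of macrophages, by 1.98 ± 0.24, while Acacb, which makes malonyl-CoA, fell by 1.54 ± 0.19. Each of these calls held with median-ratio scaling.

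The tests that follow were all chosen after the result was seen, and some were revised after their results were seen. A test that left out the 1000 genes with most input reads was replaced by one that left out 12, a test on Glycam1 by one on the fixed T and B cell list, and a test of 1 offset by the gap between pairs. Bounds of a pair of the tests were set afterwards.

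The median input gene was lower in WT cold than in WT RT (-0.67) and higher in inputs labelled cKO than in WT cold (0.40). A larger share of reads on mitochondrial mRNAs, Lars2 and Gm20594 would bring the cold median near 0, but scaling to the other reads left -0.466. Leaving out the 12 genes with most input reads, 13.5% of reads in WT RT and 37.1% in WT cold, left -0.312, and leaving out 100, 500 and 1000 left -0.22, -0.129 and -0.087, though with many genes left out the rest are centred whatever the cause, so this cannot be told apart. The series of library codes does not account for the cKO median, which lies within 1 series (0.402), and for the cold median it cannot be told apart, since cKO cold against WT RT gave -0.242. Input values are shares of the reads on the listed genes, so a lower median gene goes with other genes taking more reads. A broad change of total RNA in the cold cannot show in such values and was not tested.

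T and B cell markers were high in WT RT input and near 0 in cold input, yet present in every footprint library. Loss of lymphocytes in the cold from tissue that gave both input and footprints predicts footprint over input ratios like those of other cell types. The median log2 ratio was 4.53 in WT cold, above each other list. Macrophage markers stood at 2.65, neutrophil and mast cell markers at 2.62, fibroblast markers at 1.45 and adipocyte markers at 0.59. Skeletal muscle markers stood at 0.39 and endothelial markers at -0.27. These lists differ widely, so no single value stands for other cell types. Lymph node tissue in the pieces that gave the WT RT inputs and the cold footprints would bring the markers into all 4 footprint libraries, where 18 of 18 stood at 1 RPKM or more, but this restates what had been seen. That explanation therefore cannot be told apart from others, and the labels do not say how the tissue was taken.

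The median change of m6A enrichment over adipocyte markers was -0.57 in libraries labelled cKO, with 0 of 22 called. Spread between library pairs would make conditions overlap, but the lowest WT cold pair lay 0.3 above the highest cKO pair, with only 2 pairs per condition, a list picked from 33 for its size, and a camera adjusted p = 0.963 with an estimated correlation (0.642 with pairs as blocks). A trend on input change, level or enrichment would remove the effect, but -0.38 remained, under all 10000 random lists. The same correction put the thermogenic list at -0.48, also under all of them, and lipogenesis at -0.26. What remained is thus not particular to the white and general adipocyte list. Macrophage, fibroblast and endothelial markers lay the other way, at 0.5, 0.47 and 0.16. Before the correction the macrophage, fibroblast and endothelial medians were -0.07, 0.03 and -0.03. The thermogenic median was then -0.21, at the 12.4th percentile of random lists. The trend uses the same input libraries, in which thermogenic genes were lower and most macrophage and fibroblast markers higher with the cKO label. The correction can thus itself push such lists apart, so the split between them is not read as a result. For the same reason the -0.38 does not exclude a trend. Loss of Mettl3 from adipocytes was taken to predict a fall of the m6A-enriched genes against others. Their difference of -0.031 cannot be told apart from no effect. With pairs as blocks 76 of these 850 genes were lower and 1 higher, against 397 and 8 of all 13062. The set comes from whole WT RT tissue, where adipocyte markers lay at -0.13 and -0.08 from all genes, while Cre acts in adipocytes. The test therefore cannot decide, and loss of Mettl3 stays open as an explanation.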
